A study of Homo sapiens with 12 samples.

How the data were processed

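Polyadenylated RNA was sequenced from 12 samples of MCF7, an established estrogen receptor-positive human breast cancer cell line. The labels place 4 samples in a control group, 4 in a group overexpressing wild-type SOD2 (WT-SOD2) and 4 in a group overexpressing NLS-SOD2. SOD2 encodes the mitochondrial manganese superoxide dismutase, and NLS is the usual abbreviation of nuclear localization signal. Per the labels' protocols, RNA was extracted with the RNeasy mini plus kit and libraries were made with a stranded TruSeq mRNA kit. Groups and replicate numbers came from the sample titles. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The labels give no sequencing batch or date.

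The deposited values were raw read counts per Ensembl gene ID, 1 file per sample with 35700 IDs, and the files held no rows of unassigned reads. Per the submitters' processing notes, the tools used on the reads included cutadapt 1.13, STAR, HTSeq 0.6.1p1 and DESeq2 1.14.1, with genome build hg38. The annotation release and the strand setting of the counting were not given in the sources used here. Reads of overlapping genes on opposite strands, such as SOD2 and WTAP, are therefore uncertain, as are genes with near-identical copies: the HLA, metallothionein, UGT2B, KRAB zinc finger and histone genes. Counting without strand, or splitting reads between copies, would move such values. A table of gene names paired 24054 IDs with symbols, GENCODE 29 named 581 more, and 11065 stayed without a symbol. Coordinates are those of GENCODE 29 on GRCh38.

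Total counts ranged from 4876577 to 11547037 in control, from 13663604 to 20667171 in WT-SOD2 and from 12075988 to 13670860 in NLS-SOD2, so every WT-SOD2 and NLS-SOD2 library was deeper than every control library. The 13 protein-coding genes of the mitochondrial genome were listed at 0 counts in every library and could not be tested. The counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr (minimum count 10), which kept 13637, and libraries were scaled by TMM factors. A single quasi-likelihood model with 1 mean per group was fitted to all 12 samples (glmQLFit with robust estimation and glmQLFTest), so the 3 comparisons share 1 estimate of the spread. Adjusted p is the Benjamini-Hochberg value from this edgeR test over all genes tested, and a gene was called changed when it was under 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Group levels are means of CPM, the counts scaled to a common library total after TMM scaling, with the standard deviation (SD) over 4 samples. The common biological coefficient of variation was 0.0493. Principal components used log2 CPM with a prior count of 0.5. SOD2 was also tested by a two-sided exact permutation test, for which 4 samples against 4 allow a p no smaller than 0.0286.

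The groups, the tests, 26 gene lists, the rule for naming genes and all alternatives except those named as added were fixed before the data were examined. The lists were NRF2 target genes, other antioxidant enzymes, nuclear-encoded respiratory chain, mitochondrial genome protein-coding genes, luminal epithelial lineage, estrogen receptor target genes, basal epithelial lineage, epithelial-mesenchymal transition, stem cell and pluripotency factors, glycolysis, hypoxia response, iron handling, cell cycle, p53 target genes, interferon response, NF-kB and inflammatory genes, unfolded protein and ATF4 response, histone methylation enzymes, cholesterol synthesis, metallothioneins, cell-cell junctions, immediate early genes, replication-dependent histone genes, and markers of immune cells, fibroblasts and endothelium. Some lists share genes: 12 of the 32 hypoxia genes, 7 of the 24 glycolysis genes and 8 of the 35 luminal genes stand in another list. For the histone genes 16 of 37 symbols were found in the files, which is a minority, so that list covers part of the family. Because polyadenylated RNA was sequenced, its values do not measure histone transcripts without a poly(A) tail. Of the other-cell-type lists, 4 immune, 7 fibroblast and 7 endothelial markers had a mean CPM of 1 or more in these MCF7 samples. Lists were tested against all other genes with camera in limma at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists tested in a comparison. Camera with an estimated correlation and fry were alternatives. Fry tests whether a list's genes move, on balance, one way, and does not compare the list with other genes.

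SOD2 was named in every comparison. Also named were the 8 genes with the largest rise and the 8 with the largest fall per comparison. They came from called genes with an official symbol and a mean CPM of at least 5. Every sample of one group had to lie above every sample of the other. Pseudogenes, antisense genes, LOC, LINC and clone-type names, and names ending in -IT, -DT or -OT were left out. From each list with a called member, the 3 tested members with the smallest p could be named. Where a gene had 0 counts in a group, its fold is a bound against 3 counts over that group. Where it had 1 to 3 counts, the 95% interval of the ratio from an exact binomial interval is given. Bounds and intervals cover counting error only. In 14 list results a member had 3 or fewer counts in a group, and placing it at its bound moved 0 of the medians.

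Alternatives were DESeq2 size factors, library totals without factors, SOD2 left out of the scaling, no filter, a filter of 1 CPM in 4 libraries, the DESeq2 1.42.0 Wald test, a test against a log2 fold change of 0.5, only the 8 samples compared, the replicate number as a block, and each replicate left out in turn. Counts thinned to the smallest library, and leaving out both control 1 and NLS-SOD2 4, were added after seeing the data. The edgeR steps were tested on simulated counts with known folds, with 50 genes scored at each fold given below. A further list of genes was raised 1.5-fold together to test camera. Its genes counted among all calls, but not among the recovered or false ones. For WT-SOD2 against control, with 13466 genes in the test, they recovered 48% of genes changed 1.2-fold, 78% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, and 8% of the calls were false. For NLS-SOD2 against control the shares were 44%, 74%, 94% and 100% over 13462 genes, with 8.12% false calls. For NLS-SOD2 against WT-SOD2 they were 50%, 86%, 94% and 100% over 13471 genes, with 9.91% false calls. The shares of false calls lay above the adjusted p threshold. In the real data far more genes were called, 67.1%, 56.5% and 70.7% in the same order of comparisons. Recovery and false calls depend on the share of genes changed, so the simulated rates do not carry over to the real calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.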

Results

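Gene expression was measured by RNA sequencing in control MCF7 cells and in MCF7 cells overexpressing WT-SOD2 or NLS-SOD2, with 4 samples per group. The design asked how each form of SOD2, overexpressed, was accompanied by changes in gene expression. Total counts were lowest in control 1 (4876577) and highest in WT-SOD2 4 (20667171). The 10 most abundant genes took 3.89 ± 0.0151% of counts in control, 3.87 ± 0.047% in WT-SOD2 and 4.44 ± 0.112% in NLS-SOD2 (SD, n = 4). No 2 replicates matched within sampling noise: the chi-square statistic per degree of freedom was at least 1.7 in every replicate pair, and it was 7.18 to 8.64 in the pairs that included NLS-SOD2 4. Unless stated otherwise, levels below are mean CPM ± SD over 4 samples.

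SOD2 (ENSG00000112096, chromosome 6, 159669057 to 159745186, minus strand), the targeted gene, was highest in WT-SOD2 and intermediate in NLS-SOD2. Its level was 53.7 ± 2.9 CPM in control, 126 ± 1.55 in WT-SOD2 and 77.9 ± 3.63 in NLS-SOD2. SOD2 was 2.35-fold higher in WT-SOD2 than in control (95% interval 2.19 to 2.52, log2 fold change 1.23 ± 0.05 SE, edgeR adjusted p = 5.61e-21) and 1.45-fold higher in NLS-SOD2 than in control (1.35 to 1.56, log2 0.54 ± 0.05, edgeR adjusted p = 1.97e-10). In NLS-SOD2 it stood at 0.619 of the WT-SOD2 level (0.581 to 0.66, edgeR adjusted p = 3.71e-15). In each comparison all 4 samples of one group lay above all 4 of the other, for an exact permutation p of 0.0286, the smallest the design allows. The counts do not separate introduced from endogenous transcripts, and a construct lacking the untranslated regions would be counted only in its coding part. SOD2 overlaps WTAP (chromosome 6, 159725585 to 159756319, plus strand), which fell in WT-SOD2 (log2 −0.91 ± 0.07 SE) and rose in NLS-SOD2 (0.51 ± 0.07).

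**Figure D1:**
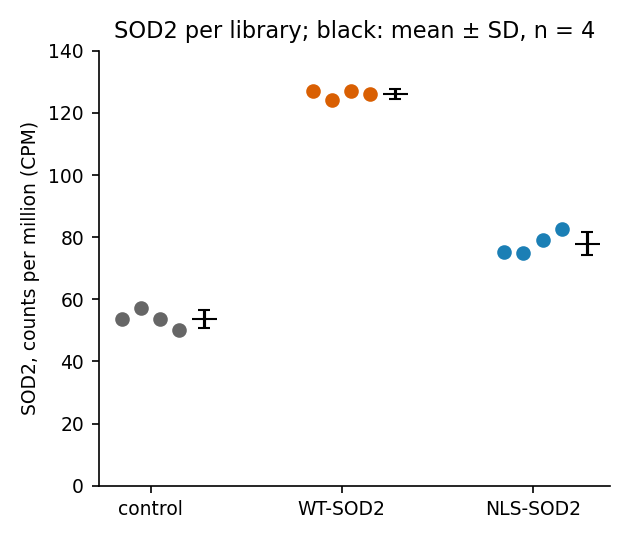
SOD2 level in each library in CPM on the vertical axis, with the 3 groups along the horizontal axis; coloured points are libraries and the black bars are the mean ± SD of 4 libraries. The WT-SOD2 libraries lie near 126 CPM, the NLS-SOD2 libraries between 75 and 82.5 CPM and the control libraries near 53.7 CPM.

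The genes around SOD2 also differed between the groups. Of the 15 neighbours within 2 Mb with a mean CPM of at least 5, a limit chosen after the values were seen, 15 were lower in WT-SOD2 than in control, with a median log2 fold change of −0.95. In NLS-SOD2, 14 of them were higher than in control and 0 were lower, with a median of 0.40 and a highest value of 0.81, so the SOD2 change of 0.54 lay inside the range of its neighbours. Over all 19 tested neighbours, 2 genes with less than 1.4 CPM, SYTL3 and OSTCP1, lay above SOD2 in WT-SOD2, with log2 fold changes of 1.83 ± 0.44 and 1.46 ± 0.54 SE.

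**Figure D2:**
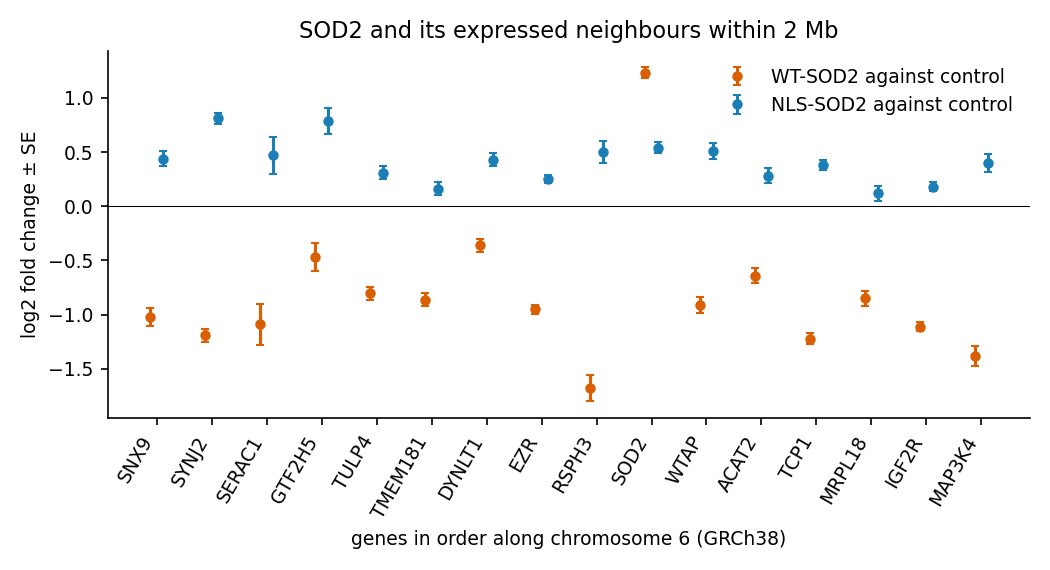
Log2 fold change against control of SOD2 and its 15 neighbours within 2 Mb that had a mean CPM of at least 5, in their order along chromosome 6; points are edgeR estimates, bars are ± 1 SE, and colours mark the comparison. In WT-SOD2 the SOD2 point (1.23) stands above neighbours that are all below 0, and in NLS-SOD2 it (0.54) stands among neighbours between 0.12 and 0.81.

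The 3 groups were well separated across genes. The first component of log2 CPM held 63.9% of the variance and placed WT-SOD2 at 75.89 to 77.5, control at −32.63 to −30.91 and NLS-SOD2 at −45.24 to −44.74. The second held 19.3% and parted control (37.35 to 41.18) from NLS-SOD2 (−36.72 to −33.23). Spearman correlations across genes were 0.993 to 0.998 within groups, 0.972 to 0.98 between control and NLS-SOD2, 0.954 to 0.957 between control and WT-SOD2 and 0.946 to 0.949 between WT-SOD2 and NLS-SOD2.

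**Figure D3:**
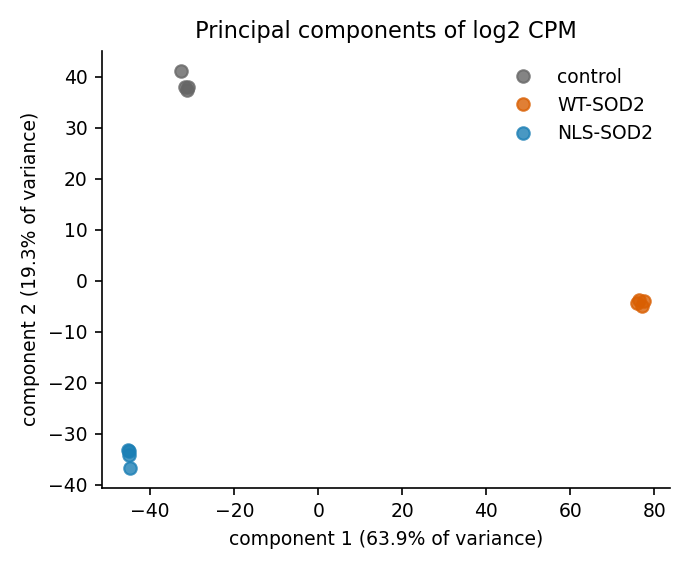
First and second principal components of log2 CPM over the 12 libraries, in arbitrary units, with the percentage of variance on each axis; each point is a library and colours mark the groups. The groups form 3 separate clusters, with WT-SOD2 apart along the first component.

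In WT-SOD2 cells, interferon response genes were higher than in control, while hypoxia and estrogen receptor target genes, glycolytic genes and inflammatory genes were mostly lower. Among genes within the naming rule (official symbol, mean CPM of at least 5, no overlap between the groups), the largest rises included MX1, an interferon-induced GTPase (31.6-fold, 48.8 ± 2.28 against 1.61 ± 0.422 CPM), the calmodulin-binding peptide gene PCP4 on chromosome 21, 39867317 to 39929397 (71.6-fold, 214 ± 4.75 against 3.16 ± 0.791) and BMP5, a bone morphogenetic protein (64.8-fold, 64.4 ± 1.98 against 0.975 ± 0.146). The largest falls by that rule included C14orf132 on chromosome 14, 96039324 to 96093889, 686-fold lower (0.268 ± 0.0604 against 185 ± 4.51 CPM), the glutamate transporter gene SLC1A1, 312-fold lower (0.0569 ± 0.0677 against 22.3 ± 0.85), and COLEC12, a scavenger receptor gene on chromosome 18, 316740 to 500722, with 1 count in WT-SOD2 against 747 in control, a ratio with an interval of 1.79e-05 to 0.00396. XIST, the noncoding RNA of X inactivation, was 269-fold higher (158 ± 1.95 against 0.597 ± 0.356 CPM). The other genes with the largest rises by that rule were FBLN1, REG4, RTL9 and GNB4 (29.6- to 62.8-fold), and those with the largest falls were SLC17A9, SLC27A6, UGT2B15, LRATD1 and FAM83E (69.7- to 161-fold). Across all genes 9153 of 13637 (67.1%) were called changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4553 higher and 4600 lower, and 1973 of them changed at least 2-fold (1051 higher, 922 lower). Without control 1, the shallowest library, and NLS-SOD2 4, which stood apart from its replicates, 9487 genes were called, of which 8982 were among the 9153.

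Of the 38 tested interferon response genes 37 rose and 1 fell, and the median log2 fold change was 2.55. IFI6 rose 9.42-fold (380 ± 7.26 against 40.4 ± 1.41 CPM) and OAS3, an enzyme that senses double-stranded RNA, 3.98-fold (372 ± 8.85 against 93.2 ± 3.2). Camera gave an adjusted p of 9.27e-41 for the list, and the call held with an estimated correlation (adjusted p = 0.0109). Of the 4 tested immune cell markers 2 rose and 2 fell, and that list was not called.

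Of the 30 tested hypoxia response genes 20 fell, 4 rose and 6 did not pass (median −0.48). STC2, a secreted glycoprotein that is also an estrogen receptor target, fell 2.92-fold (578 ± 9.84 against 1690 ± 37.7 CPM) and DDIT4, an inhibitor of mTORC1 signalling, fell 3.04-fold, while CA12, a carbonic anhydrase, rose 1.9-fold. The camera adjusted p was 0.000123 and the call held with an estimated correlation (adjusted p = 0.0109). Of the 22 tested glycolysis genes 15 fell, 4 rose and 3 did not pass, with GAPDH 1.69-fold lower (1950 ± 26.8 against 3290 ± 18.2 CPM), ENO1 1.58-fold lower and PGK1 1.64-fold lower. The camera adjusted p for glycolysis was 0.0234, and the call was lost with an estimated correlation (adjusted p = 0.363).

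Of the 35 estrogen receptor targets 19 fell, 13 rose and 3 did not pass (median −0.26). The zinc transporter gene SLC39A6 fell 4.35-fold (1170 ± 40.6 against 5100 ± 38.5 CPM) and the potassium channel gene KCNK5 fell 4.96-fold. The list passed camera (adjusted p = 0.000123) but not with an estimated correlation (adjusted p = 0.0592). Among 33 luminal lineage genes 16 fell and 9 rose, and the list was not called; TFF1, a secreted estrogen-regulated trefoil peptide, fell 7.06-fold (314 ± 13.9 against 2220 ± 82.9 CPM), the androgen receptor gene AR fell 8.93-fold and AGR2 rose 2.26-fold.

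Of the 18 tested NF-kB and inflammatory genes 11 fell, 1 rose and 6 did not pass. NFKBIA, the NF-kB inhibitor, fell 2.59-fold, the cytokine gene LIF fell 3.46-fold, and the chemokine gene CXCL8 had 3 counts in WT-SOD2 against 217 in control, a ratio with an interval of 0.0015 to 0.0217. The list had a camera adjusted p of 0.0226 and was not called with an estimated correlation (adjusted p = 0.363). Of 23 cholesterol synthesis genes 15 rose, 4 fell and 4 did not pass. LDLR, the low-density lipoprotein receptor gene, rose 2.08-fold and INSIG1 1.62-fold, whereas SQLE, an enzyme of sterol synthesis, fell 2.49-fold. The camera adjusted p was 0.0419 (adjusted p = 0.363 with an estimated correlation, and 0.0554 without control 2, which ended the call). Of the 12 tested replication-dependent histone genes 8 fell, 0 rose and 4 did not pass. H2BC21 was 1.73-fold, H4C8 2.16-fold and H2BC4 2.88-fold lower. The libraries were made from polyadenylated RNA, so these falls do not describe histone transcripts as a whole. For them camera gave an adjusted p of 0.0419, and the call was lost with an estimated correlation (adjusted p = 0.132) and without control 1 (adjusted p = 0.0527).

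The remaining lists were not called in WT-SOD2 by camera, although most held changed members in both directions. Of 25 basal lineage genes 14 rose and 7 fell (camera adjusted p = 0.0537, and 0.0466 and 0.0463 without WT-SOD2 2 and WT-SOD2 4); the cadherin gene CDH3 rose 2.85-fold, and CAV1 and CAV2, caveolin genes, rose 2.53-fold and 2.39-fold. Among the 8 tested fibroblast markers 4 rose and 1 fell, COL1A1 rising 4.72-fold (adjusted p = 0.058 by camera, and 0.0497, 0.0499 and 0.0494 without control 4, WT-SOD2 2 and WT-SOD2 4). In the epithelial-mesenchymal transition list 10 of 20 rose and 6 fell: the fibronectin gene FN1 rose 3.67-fold and INHBA 6.46-fold, and TGFB1 fell 4.02-fold. Of 25 NRF2 targets 11 rose and 8 fell, with NQO1, a quinone reductase, 2.12-fold higher (1210 ± 27 against 571 ± 8.55 CPM) and the thioredoxin reductase gene TXNRD1 1.94-fold lower. Rises and falls numbered 7 and 10 of 23 other antioxidant enzymes, 17 and 23 of 50 respiratory chain genes, 9 and 8 of 22 stem cell factors, 7 and 6 of 19 iron handling genes, 19 and 12 of 38 cell cycle genes and 14 and 8 of 27 p53 targets. They numbered 16 and 9 of 30 unfolded protein and ATF4 genes, 17 and 10 of 35 histone methylation enzymes, 3 and 0 of 3 metallothioneins, 11 and 15 of 32 junction genes, 9 and 9 of 21 immediate early genes and 4 and 1 of 8 endothelial markers. The metallothionein gene MT1F was not called without control 3 (edgeR adjusted p = 0.0637) or WT-SOD2 3 (0.0573). PSAT1, an enzyme of serine synthesis in the ATF4 list, had 0 counts in WT-SOD2 and was at least 205-fold lower than in control (9.47 ± 0.809 CPM). Adjusted over the list alone, the counts were those given over all genes, except that 11 antioxidant enzymes, 16 glycolysis genes and 16 junction genes fell. Median, mean and test differed in sign for iron handling (median 0.07, test down), the ATF4 list (0.2, −0.13 and up) and immediate early genes (−0.04, 0.14 and up).

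In NLS-SOD2 cells, inflammatory and luminal lineage genes were mostly lower than in control, and basal lineage and epithelial-mesenchymal transition genes were mostly higher. CFB and C3, complement components, were 28.4-fold lower (2.64 ± 0.695 against 75.2 ± 3.14 CPM) and 14.7-fold lower (1.03 ± 0.399 against 15.2 ± 2.11). LCN2, an iron-siderophore binding protein, was 28.1-fold lower (2.57 ± 0.58 against 72.7 ± 2.12), and TNFAIP3, an inhibitor of NF-kB signalling, 8.2-fold lower (2.65 ± 0.284 against 21.6 ± 1.45). Among genes within the naming rule, the largest rises were those of PLAC1 (11.7-fold, 18.7 ± 1.79 against 1.52 ± 0.427 CPM) and LRP1B (11.7-fold). MIR503HG came next (11.3-fold, 34.7 ± 1.59 against 2.97 ± 1.15). PPP1R1C, NGFR, HLA-DPB1, SPRR1B and ARMCX2 followed (7.73- to 8.95-fold). The other large falls by that rule were those of PCDH7, HLA-DRB1, GRIK3 and PCDH10 (7.65- to 18.3-fold). The edgeR test called 7704 of 13637 genes (56.5%), 3839 higher and 3865 lower, and 987 changed at least 2-fold (684 higher, 303 lower). Without control 1 and NLS-SOD2 4 it called 7678, of which 7076 were among the 7704.

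Of the 18 tested NF-kB and inflammatory genes 16 fell in NLS-SOD2, 1 rose and 1 did not pass (median −0.98). NFKBIA fell 1.84-fold (171 ± 3.87 against 315 ± 13.1 CPM) and IER3, an early response gene, 1.99-fold. The camera adjusted p was 1.91e-09, and with an estimated correlation the list was not called (adjusted p = 0.0575). Of 38 interferon response genes 14 rose, 7 fell and 17 did not pass, with a median log2 fold change of 0.06 and a mean of 0.41. Changes of at least 2-fold numbered 10 rises and 0 falls. OAS3 was 1.64-fold and IFI6 1.59-fold lower, and SAMD9 was 3.17-fold higher. The interferon list was not called by camera.

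Of 33 luminal lineage genes 19 fell, 5 rose and 9 did not pass. The mucin gene MUC1 fell 3.84-fold (25.6 ± 1.56 against 98 ± 1.53 CPM), CDH1, which encodes E-cadherin, fell 1.44-fold (1270 ± 14.8 against 1830 ± 18.6) and the transcription factor gene SPDEF fell 1.73-fold. Camera gave the list an adjusted p of 0.00139, and the call was lost with an estimated correlation (adjusted p = 0.174). Of 25 basal lineage genes 18 rose, 4 fell and 3 did not pass (median 0.67). NGFR, the p75 neurotrophin receptor gene, rose 8.76-fold (10.7 ± 1.2 against 1.12 ± 0.541 CPM), the transcription factor gene TP63 7.27-fold and the keratin gene KRT6A 6.12-fold. The basal list passed camera (adjusted p = 0.000409) also with an estimated correlation (adjusted p = 0.0337).

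In the epithelial-mesenchymal transition list 11 of 20 tested genes rose, 4 fell and 5 did not pass (median 0.46). TGFB2, a growth factor gene, rose 3.29-fold (106 ± 6.38 against 32.2 ± 1.69 CPM), COL5A2 5.16-fold and COL6A2 2.33-fold. Its camera adjusted p was 0.000115, and the call held with an estimated correlation (adjusted p = 0.0236). Of the 8 tested fibroblast markers 3 rose, 1 fell and 4 did not pass, with a mean log2 fold change of 0.81 and a median of −0.04. The 2 lists are not fully separate from the others: 3 of the 20 fibroblast markers and 5 of the 35 epithelial-mesenchymal transition genes stand in another list. COL5A1 rose 4.3-fold (248 ± 4.9 against 57.5 ± 2.88 CPM) and COL1A1 2.71-fold, and LUM had 76 counts against 1 in control, a ratio with an interval of 8.9 to 2050. The fibroblast list had a camera adjusted p of 0.00296, and the call was lost with an estimated correlation (adjusted p = 0.174) and without control 1 and NLS-SOD2 4 (adjusted p = 0.0513). Of the 4 immune markers 2 rose and 1 fell, and of the 8 endothelial markers 2 rose and 2 fell, and neither list was called. The immune marker that fell, LAPTM5, was not called without control 1 (edgeR adjusted p = 0.0994), control 2 (0.134), NLS-SOD2 1 (0.0607), NLS-SOD2 3 (0.0582) or NLS-SOD2 4 (0.0824), nor without control 1 and NLS-SOD2 4 together (0.171).

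Hypoxia response genes rose more often than they fell, 15 against 9 of 30, with NDRG1 2.1-fold, DDIT4 1.8-fold and the mitophagy receptor gene BNIP3L 1.64-fold higher. By camera the adjusted p was 0.0411, and the call was lost with an estimated correlation (adjusted p = 0.178) and without control 2 (0.0557) or control 4 (0.0514). Of 38 cell cycle genes 17 fell, 12 rose and 9 did not pass (median −0.07). MCM3 and MCM4, subunits of the replicative helicase, fell 2.03-fold (137 ± 1.66 against 279 ± 7.93 CPM) and 1.54-fold, and the transcription factor gene E2F1 fell 2.01-fold. The list had a camera adjusted p of 0.0466, and the call was lost with an estimated correlation (adjusted p = 0.174). It was also lost without control 4 (0.0526), NLS-SOD2 1 (0.0647), NLS-SOD2 2 (0.0561) or NLS-SOD2 3 (0.0738), and without control 1 and NLS-SOD2 4 together (0.0519). Of 23 cholesterol synthesis genes 13 fell, 5 rose and 5 did not pass, with LSS 1.86-fold, DHCR24 1.54-fold and DHCR7 1.37-fold lower. For them camera gave an adjusted p of 0.0276, and the call was lost with an estimated correlation (adjusted p = 0.273).

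The other lists were not called in NLS-SOD2. NQO1 fell 1.9-fold (301 ± 15.6 against 571 ± 8.55 CPM), among 8 rises and 9 falls of 25 NRF2 targets, and TXNRD1 rose 1.39-fold. Rises and falls numbered 9 and 9 of 23 antioxidant enzymes, 8 and 21 of 50 respiratory chain genes, 17 and 12 of 35 estrogen receptor targets, 8 and 9 of 22 stem cell factors, 6 and 10 of 22 glycolysis genes and 6 and 6 of 19 iron handling genes. They numbered 13 and 8 of 27 p53 targets, 13 and 9 of 30 unfolded protein and ATF4 genes, 8 and 12 of 35 histone methylation enzymes, 0 and 2 of 3 metallothioneins, 12 and 10 of 32 junction genes, 8 and 8 of 21 immediate early genes and 0 and 6 of 12 histone genes. Of the metallothioneins, MT1X was not called without control 1 (edgeR adjusted p = 0.0775), control 2 (0.0829), control 4 (0.193), NLS-SOD2 2 (0.0846) or NLS-SOD2 4 (0.103), nor without control 1 and NLS-SOD2 4 together (0.165), which left 1 fall. The cystine transporter gene SLC7A11 rose 3.37-fold, the chaperone gene HSPA5 1.4-fold and DSC2, a desmosomal cadherin gene, 3.3-fold. Adjusted over the list alone, the counts were those over all genes, except that 14 histone methylation enzymes fell and 13 junction genes rose. Besides the fibroblast markers, the median, mean and test differed in sign for NRF2 targets (−0.03, 0.07 and down), antioxidant enzymes (−0.01, 0.01 and down) and stem cell factors (−0.01, 0.27 and up).

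Compared with each other, NLS-SOD2 cells had lower levels of interferon response genes and of most cholesterol synthesis and cell cycle genes than WT-SOD2 cells, and higher levels of most hypoxia and estrogen receptor target genes. C14orf132 was 1680-fold higher in NLS-SOD2 (454 ± 22.2 against 0.268 ± 0.0604 CPM) and SLC1A1 553-fold higher. WDR72 and the GABA receptor gene GABRB3 had 0 counts in WT-SOD2 and were at least 272-fold and at least 251-fold higher in NLS-SOD2. With 1 to 3 counts in WT-SOD2, CCDC85A had a ratio with an interval of 241 to 53300, COLEC12 of 186 to 41100, SPRR1B of 132 to 29100 and ADAM2 of 98.9 to 1410. In the other direction, ZNF738 and the secreted lectin gene REG4 had 0 counts in NLS-SOD2 and were at least 207-fold and at least 179-fold lower, and XIST had 1 count in NLS-SOD2, a ratio with an interval of 3.11e-06 to 0.000685. MAOB, a monoamine oxidase, was 271-fold lower, BMP5 179-fold, FBLN1 78.5-fold, RAMP3 42.1-fold (2.57 ± 0.763 against 108 ± 5.62 CPM) and GNB4 39.3-fold. The edgeR test called 9645 of 13637 genes (70.7%), 4813 higher and 4832 lower in NLS-SOD2, and 2121 differed at least 2-fold (1233 higher, 888 lower). Without control 1 and NLS-SOD2 4 it called 9963, of which 9327 were among the 9645.

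All 38 interferon genes tested were lower in NLS-SOD2 than in WT-SOD2 (median −1.98), with IFI6 15-fold, OAS3 6.51-fold and MX1 30.4-fold lower. With camera the list reached an adjusted p of 6.77e-35 and the call held with an estimated correlation (adjusted p = 0.000168). Of 30 hypoxia genes 25 were higher, 2 lower and 3 did not pass (median 0.62): DDIT4 was 5.49-fold higher (248 ± 8.08 against 45.1 ± 1.2 CPM), STC2 2.98-fold higher and CA12 1.68-fold lower. This list passed camera (adjusted p = 2.4e-07) also with an estimated correlation (adjusted p = 0.00183). Of 35 estrogen receptor targets 21 were higher, 10 lower and 4 did not pass (median 0.27), with SLC39A6 5.37-fold (6310 ± 279 against 1170 ± 40.6 CPM) and ASCL1, a transcription factor gene, 74.8-fold higher. Camera gave the list an adjusted p of 1.76e-05, and the call held with an estimated correlation (adjusted p = 0.0368).

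Of 38 cell cycle genes 21 were lower, 4 higher and 13 did not pass, with MCM3 1.56-fold, the replication licensing gene CDT1 1.77-fold and CDK2 1.57-fold lower. By camera the adjusted p was 0.024, and the call was lost with an estimated correlation (adjusted p = 0.0826). Of 23 cholesterol synthesis genes 15 were lower, 3 higher and 5 did not pass (median −0.65), with LDLR 2.29-fold and LSS 2.4-fold lower and SQLE 2.39-fold higher. The list had a camera adjusted p of 0.000394, and the call was lost with an estimated correlation (adjusted p = 0.119). Junction genes, 17 higher and 10 lower of 32, were not called by camera (adjusted p = 0.188), but were without NLS-SOD2 4 (0.0496) and without control 1 and NLS-SOD2 4 together (0.0465); DSC2 was 10.5-fold higher (43.3 ± 4.59 against 4.01 ± 0.823 CPM).

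The remaining lists were not called between NLS-SOD2 and WT-SOD2. NQO1 was 4.02-fold lower, among 7 higher and 14 lower of 25 NRF2 targets. Higher and lower genes numbered 9 and 8 of 23 antioxidant enzymes, 15 and 19 of 50 respiratory chain genes, 12 and 17 of 33 luminal genes, 10 and 9 of 25 basal genes, 9 and 7 of 20 epithelial-mesenchymal transition genes and 9 and 10 of 22 stem cell factors. They numbered 14 and 5 of 22 glycolysis genes, 6 and 10 of 19 iron handling genes, 9 and 15 of 27 p53 targets, 4 and 9 of 18 NF-kB and inflammatory genes, 11 and 12 of 30 unfolded protein and ATF4 genes and 12 and 16 of 35 histone methylation enzymes. For 3 metallothioneins they were 0 and 3, for 21 immediate early genes 9 and 11, for 12 histone genes 6 and 0, for 4 immune markers 3 and 0, for 8 fibroblast markers 3 and 4 and for 8 endothelial markers 2 and 4. MT1F was not called without WT-SOD2 3 (edgeR adjusted p = 0.0806) or NLS-SOD2 4 (0.0848), nor without control 1 and NLS-SOD2 4 together (0.0812). TRIM29 was 6.01-fold higher, CDH3 2.67-fold lower, TGFB1 4.54-fold higher, the efflux transporter gene ABCG2 7.85-fold higher and the death receptor gene FAS 6.35-fold lower. Adjusted over the list alone, the counts were those over all genes, except that 15 NRF2 targets, 10 basal genes, 8 epithelial-mesenchymal transition genes and 17 histone methylation enzymes were lower and 3 endothelial markers were higher. Median, mean and test differed in sign for NRF2 targets (−0.19, 0.02 and down), respiratory chain genes (−0.01, −0.01 and up), epithelial-mesenchymal transition genes (−0.11, 0.01 and up), stem cell factors (−0.22, 0.14 and down), the ATF4 list (−0.05, 0.32 and up) and endothelial markers (0.07, 0.06 and down).

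**Figure D4:**
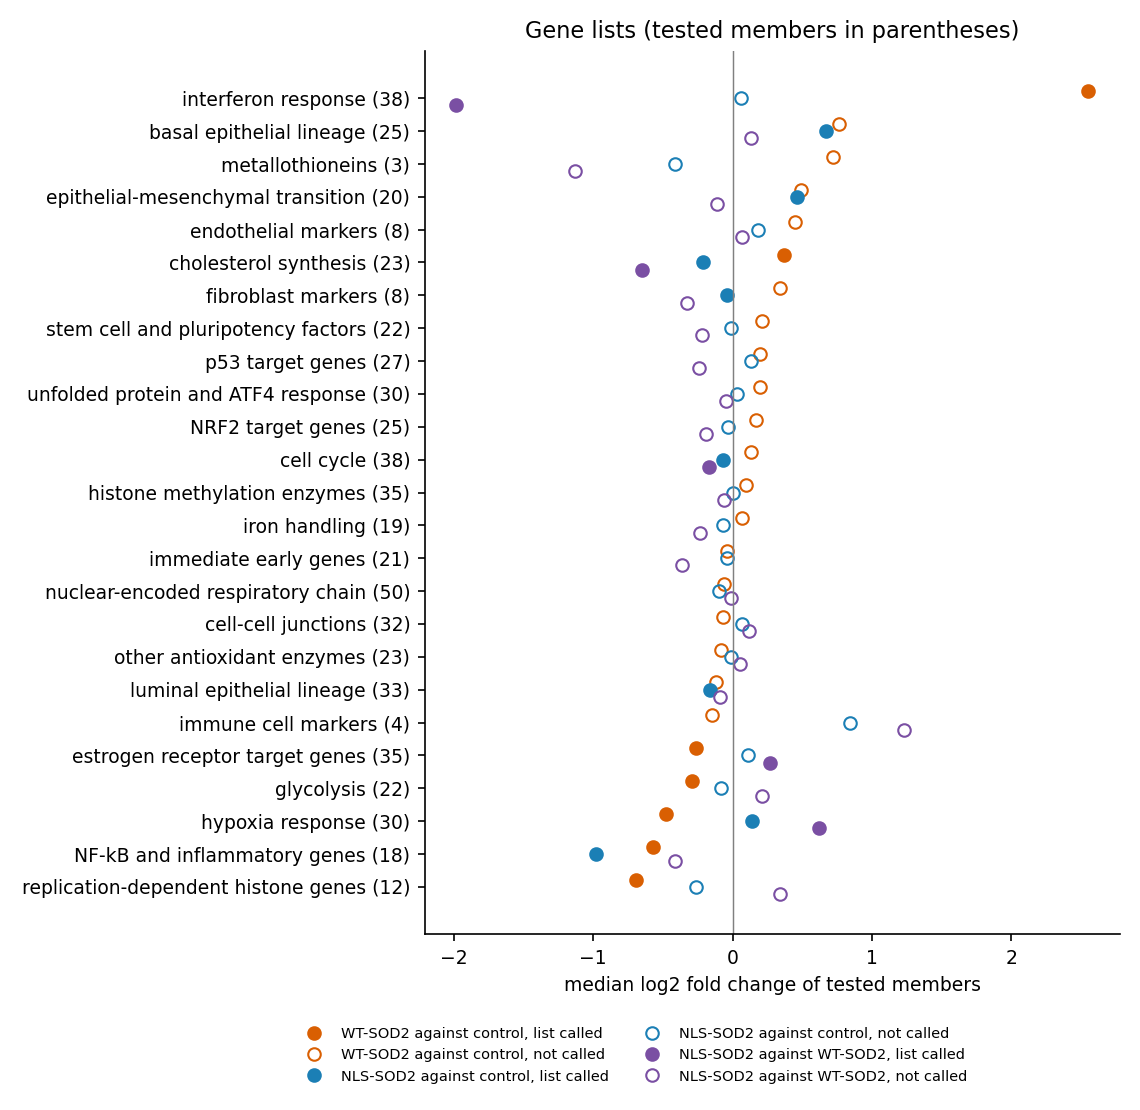
Median log2 fold change of the tested members of each gene list, one line per list, with the number of tested members in parentheses; colours mark the 3 comparisons and filled points mark lists called by camera at the preset correlation. The interferon list lies at 2.55 in WT-SOD2 against control, near 0 in NLS-SOD2 against control and at −1.98 in NLS-SOD2 against WT-SOD2.

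The changes against control overlapped between the SOD2 forms. A total of 3779 genes changed in the same direction in WT-SOD2 and NLS-SOD2 (1738 higher, 2041 lower), where independent lists would share 1282 and 1304, and 1859 changed in opposite directions, where independent lists would give 2585. Both comparisons use the same control libraries. In 20 simulations of unchanged groups against them 0 calls were shared, but such groups give almost no calls, so this does not measure how far the shared controls raise the overlap. With the controls split so that each comparison had its own 2, the median over the 6 splits was 2980 genes in the same direction. Independent lists would share 937.65 higher and 1014.5 lower. In opposite directions the median was 1465.5, where they would give 1952.5. The split removes only the noise of shared libraries. All control libraries come from the same group, so a difference particular to that group would still enter both comparisons in the same direction. The correlation of the fold changes across genes, which are not independent replicates, was 0.182 against 0.6017 in the simulations. The simulated groups held no real changes, so their correlation reflects only the noise of the shared controls. The 2 correlations are therefore not comparable, and the lower observed value does not show less sharing than by chance. The covariance of the fold changes was 0.1207 against 0.0207 in the simulations, a difference of 0.1. LCN2, the iron-siderophore binding gene, was among the shared falls (29.8-fold in WT-SOD2 and 28.1-fold in NLS-SOD2), and NQO1 was among the genes that moved in opposite directions.

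Changes were also arranged along chromosomes, in a measurement chosen after the data were seen. In WT-SOD2, 346 of the 455 tested genes on chromosome 14 fell and 29 rose, with a median log2 fold change of −0.59, and this chromosome holds C14orf132. On chromosome 11, 487 of 745 genes rose and 94 fell (median 0.42), and medians were −0.27 on chromosome 5 and −0.24 on chromosome 8. In NLS-SOD2 against control the median of chromosome 14 was 0.05. Of 238 windows of 10 Mb, 38 had a median of 0.4 or more in either direction in WT-SOD2 and 2 in NLS-SOD2, both against control. When the regional median of each gene was subtracted, the medians of some lists moved. In WT-SOD2 against control the interferon median went from 2.55 to 2.41, that of hypoxia genes from −0.48 to −0.30 and that of cholesterol synthesis genes from 0.37 to 0.24. In NLS-SOD2 against control, cholesterol synthesis went from −0.21 to −0.11, cell cycle genes from −0.07 to −0.11 and fibroblast markers from −0.04 to 0.05. In NLS-SOD2 against WT-SOD2, cell cycle genes went from −0.17 to −0.27, and the medians of uncalled lists changed sign, leaving out any that rounded to 0.00 before or after, for epithelial-mesenchymal transition (−0.11 to 0.37), basal lineage (0.13 to −0.11) and respiratory chain (−0.01 to 0.05). Among uncalled lists against control, with the same exception, the sign changed for immediate early genes (−0.04 to 0.05) and immune markers (−0.15 to 0.02) in WT-SOD2, and for NRF2 targets (−0.03 to 0.05), junction genes (0.07 to −0.05) and immediate early genes (−0.04 to 0.03) in NLS-SOD2. Medians of the other called lists kept their sign and moved by less than 1.5 times, and the lists were not tested again after the subtraction. Some uncalled lists moved toward 0. Metallothioneins went from 0.72 to 0.27 in WT-SOD2 against control. In NLS-SOD2 against WT-SOD2 they went from −1.13 to −0.67, and NRF2 targets from −0.19 to −0.00. Others moved away from 0, such as junction genes (−0.07 to −0.20) and luminal genes (−0.12 to −0.23) in WT-SOD2 against control.

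**Figure D5:**
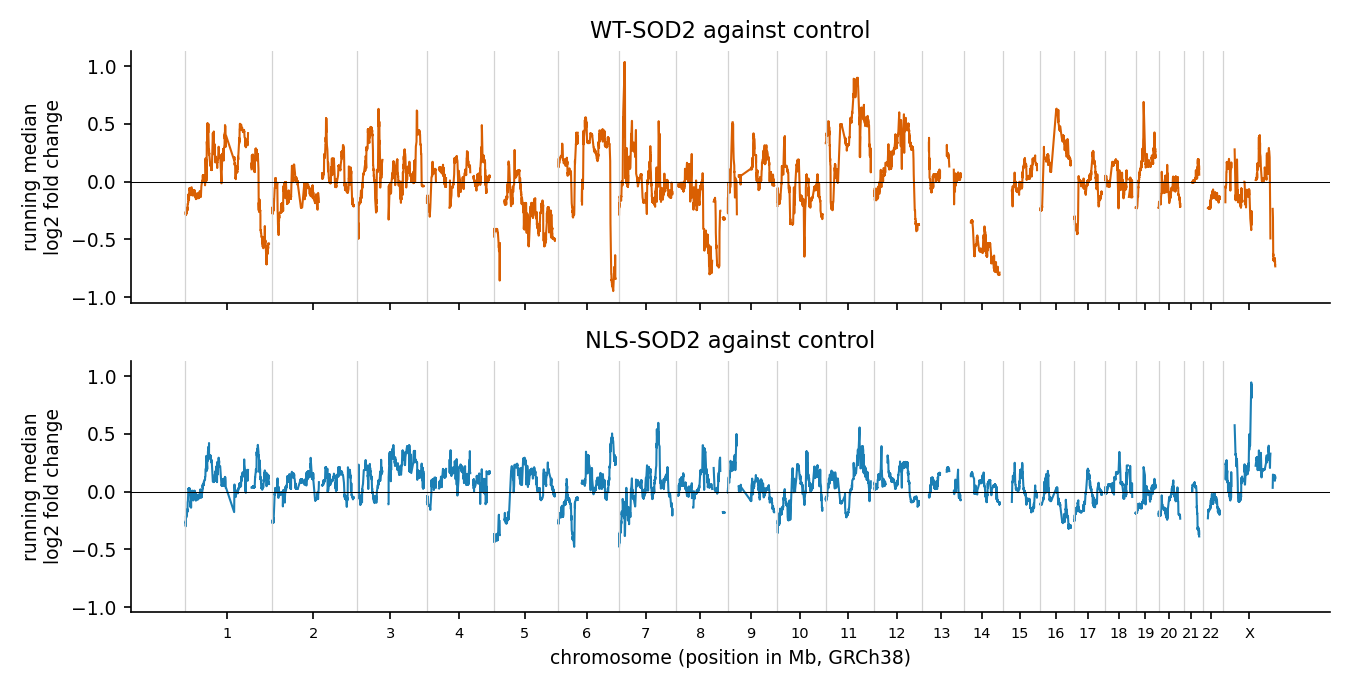
Running median of the log2 fold change against control over genes within 5 Mb of each gene, along chromosomes 1 to 22 and X in GRCh38, with WT-SOD2 in the upper panel and NLS-SOD2 in the lower. Long stretches lie away from 0 in WT-SOD2, including all of chromosome 14, whose median is −0.59.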

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

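The test used here was planned and was applied to the total counts and to 103 genes that the text names by the naming rule, XIST left out, in each group with at least 4 counts of the gene. In a group of 4, a library counted as apart when its gap to the nearest of the others, as a share of the range of the group, exceeded Dixon's 95% critical value. Of 299 groups tested 16 held such a library, and chance alone gives about 1 in 20 groups, here 14.9.

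NLS-SOD2 4 stood apart in 5 of them. It had 97.2 CPM of CDK2 against 100 in the others, 2710 CPM of GAPDH against 2990 to 3020, 101 CPM of H2BC21 against 112, 6720 CPM of SLC39A6 against 6130 to 6220, and 882 CPM of TXNRD1 against 775 to 790. In the other NLS-SOD2 libraries, NLS-SOD2 2 had 32.2 CPM of ABCG2 against 33.5 to 33.6, NLS-SOD2 3 had 691 CPM of PGK1 against 652 to 659, and NLS-SOD2 1 had 0.293 CPM of CXCL8 against 0.

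WT-SOD2 4 had a total of 20667171 counts against 13663604 to 14652460 in the others, and 76.8 CPM of BNIP3L against 74.9 to 75. WT-SOD2 2 had 8.55 CPM of COL5A2 against 10.7 to 11.1, 19.1 CPM of FBLN1 against 21.1 to 21.2 and 11.2 CPM of TNFAIP3 against 14.6 to 15.1. WT-SOD2 3 had 42.8 CPM of PCDH10 against 46.6 to 47.3. Control 4 had 24.1 CPM of COLEC12 against 20.3 to 20.9 and 8.27 CPM of PSAT1 against 9.73 to 10.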

How the results depend on the processing

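The thinned counts and the fit without control 1 and NLS-SOD2 4 were chosen only after the data were seen; the other alternatives were planned. No result reversed. Tested against a log2 fold change of 0.5, edgeR's glmTreat called 3221 genes in WT-SOD2 against control, 1424 in NLS-SOD2 against control and 3592 in NLS-SOD2 against WT-SOD2, fewer than against 0 by the construction of the test. Lists called numbered 7, 8 and 5 with camera, 2, 2 and 3 with an estimated correlation, and 22, 20 and 21 with fry, which asks another question. Under the other settings the numbers of changed genes lay within 1.5 times the main ones: 9016, 7567 and 9465 with DESeq2, 9156, 7704 and 9658 with its size factors, 9278, 7817 and 9688 with totals only, 9657, 7891 and 10299 without a filter, 7879, 6530 and 8088 with thinned counts. Each replicate left out in turn gave 8779 to 9017, 7161 to 7834 and 9295 to 9899. With totals only, the share of calls that were higher was 58.3%, 57% and 46.6% against 49.7%, 49.8% and 49.9%, and the median over all genes moved by at most 0.083 on the log2 scale. Log2 fold changes of SOD2 ranged from 1.18 to 1.31, from 0.48 to 0.59 and from −0.73 to −0.68. Of 4745 alternative values for 264 named gene results, 4724 kept their side of the threshold and 21 lost significance, all of them for MT1F, MT1X or LAPTM5. Those genes were named for small p or large changes in the main fit, so these numbers do not describe genes in general. Of 975 alternative values for the lists, 901 kept their side of the threshold, 24 lost the call and 50 gained it. Leaving out a replicate ended 8 calls and added 6. The other alternatives ended 16 and added 44. Nearly all of those 44 came with fry, so the pooled gains do not show that camera calls strengthened. Among values that passed in neither fit the direction could differ. With fry, for example, uncalled immediate early genes in WT-SOD2 against control went from up to down. The replicate numbers do not pair the samples: same-numbered samples of different groups had correlations of −0.026 to 0.039 in their deviations from the group means, others −0.052 to 0.052, and 3 of 12 samples correlated best with their own number. With the replicate block 9127, 7703 and 9626 genes were called, and of the lists the cell cycle in NLS-SOD2 against control was not called (camera adjusted p = 0.0645; 1.07e-06 with fry to 0.174 over its alternatives). Fewer genes were called with thinned counts, so depth limits the number of calls. Without control 1, the smallest library, 9017 genes were called in WT-SOD2 and 7499 in NLS-SOD2, both against control.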

Other observations

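All tests below were chosen only after the data were seen. For the comparison of the numbers of changed genes at equal depth, the bound was set before its value was seen.

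A set of genes was close to absent in one group and expressed in another, by limits of 0.1 and 5 CPM set after the data were seen. Between NLS-SOD2 and WT-SOD2, 22 genes were expressed in NLS-SOD2 and under 0.1 CPM in WT-SOD2, and 8 genes were the reverse. Control lay between both in 20 of the 22 and in 6 of the 8. The genes were chosen for values at both ends, which makes a control value in between likely. These counts therefore do not show that the SOD2 forms moved genes in opposite directions. Examples, chosen after their values were seen, are PTHLH, the parathyroid hormone-related protein gene (9.12 CPM in NLS-SOD2, 2.92 in control and 0.0285 in WT-SOD2), CLDN1, a tight junction gene (11.6, 2.17 and 0.0712), and HTR2C, a serotonin receptor gene (10.3, 3.86 and 0.0568). Genes expressed in WT-SOD2 and close to absent in NLS-SOD2 included ZNF257 (5.59 CPM in WT-SOD2, 0.133 in control and 0 in NLS-SOD2) and TMEM26 (8.98, 0.764 and 0.0207). Against control, 9 genes expressed in control were under 0.1 CPM in WT-SOD2, among them KCNMA1, a potassium channel gene (9.8 CPM in control and 0.0617 in WT-SOD2), and 2 appeared, ZNF486 (0.054 and 5.92) and ENSG00000165659, which had no symbol (0 and 19.1). In NLS-SOD2, COL26A1 (0 in control and 6.06) and EFCAB3 (0 and 7.63) appeared, and CXCL8 (6.11 and 0.0732) and CT83 (9.28 and 0.0187) were close to absent. A count of 0 over the 4 libraries of a group allows a level of up to that of 3 counts, 0.0868 CPM in control, 0.046 in WT-SOD2 and 0.0584 in NLS-SOD2, for counting error only.

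SOD2 rose 2.35-fold in WT-SOD2 and 1.45-fold in NLS-SOD2, and its neighbours on chromosome 6 moved as well. In WT-SOD2 a shift of the region does not account for the rise: SOD2 exceeded the highest of its 15 expressed neighbours by 1.59 on the log2 scale, while all 15 fell, and WTAP reads counted as SOD2 are argued against by the fall of WTAP itself (−0.91). Over all 19 neighbours 2 low-count genes lay above SOD2, and the expression limit was set after seeing them. In NLS-SOD2 SOD2 lay −0.27 from the highest neighbour, that is inside their range, so a shift of the region stays open as an explanation for that rise. WTAP rose in NLS-SOD2 as well (0.51 ± 0.07 SE), so WTAP reads counted as SOD2 also stay open there. The overexpression named by the labels, from a construct whose reads may be counted only in part, is the untested biological alternative.

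Genes close to each other on a chromosome moved together. Across genes, the log2 fold change of a gene correlated with the mean of genes 5 to 10 Mb away at 0.297 in WT-SOD2 and 0.171 in NLS-SOD2, both against control, while the highest of 1000 shuffled gene orders reached 0.034 and 0.038 (permutation p = 0.001, the smallest they can give). GC content and transcript length are argued against as the whole cause, since the correlation after a fit on both was 0.315 and 0.14. Block shifts such as copy number differences between the cell populations may account for the pattern, and DNA was not analysed here, so a regional effect of SOD2 itself stays open and untested. Regional medians held 7.02% and 2.78% of the variance of the fold changes, and 78.5% and 88.2% of the genes changed at least 2-fold stayed so after their subtraction.

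The number of changed genes was large in every comparison. Of the 35 splits of the 8 samples into 4 and 4, 1 in each comparison, the real one, gave as many genes (9153, 7704 and 9645). The highest of the others gave 0. Mixed splits have the group difference in their residual spread, so 0 calls follow from the clear separation of the groups. The splits thus show only that the samples part along the labelled groups. Chance differences between cultures are not excluded, since the replicates may be technical. Lower depth of the control libraries is argued against as the cause, since with every library thinned to the smallest total 7879 genes changed in WT-SOD2 and 6530 in NLS-SOD2, both against control. Differences between cell populations that arose apart from SOD2, for which the labels give no separate control lines, may contribute and were not tested. The overexpression itself stays open as the explanation the design names.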
